A study of Mus musculus with 16 samples.

How the data were processed

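RNA from efferent duct and caput epididymis of adult male mice had been hybridized to 16 one-colour Affymetrix mouse arrays with 45101 probe sets, 8 arrays per tissue. The labels give 4 treatments per tissue in duplicate, and the groups compared were taken from them. Per the labels' protocols, total RNA was extracted with TRIzol, and 50 ng was labelled with the Ovation system for the efferent duct and 10 µg with the One-Cycle kit for the caput. Tissue and kit therefore changed together. The labels do not state that replicates came from separate animals, so p-values then measure only the spread between these samples.

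The deposited intensity values were on a linear scale. Per the submitters' processing notes they were made with RMA, with no version given. The deposited values did not have the form RMA output usually has: they were not log2 values, each array had a mean of 125 after trimming 2% of probe sets at each end, and the quantiles differed between arrays, as with Affymetrix's own scaling. They were used as linear intensity. Log2 was taken of the deposited intensity here before any test.

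Probe sets were joined to gene symbols with the platform annotation: 34958 had 1 symbol, 932 several and 9211 none, and only the first kind was used. For 9010 genes with more than 1 probe set, the brightest over all arrays was kept, which left 18193 genes. Of the 10 genes to be named whatever their values, 2 had no probe set with their symbol. Background was set on each array by the highest of 27 Bacillus control probe sets, 2.33 to 14.3 in intensity. In the efferent duct it was 8.09 to 14.3 on the vehicle arrays and 2.33 to 3.97 on the hormone arrays. A group was called below background when both its arrays were under that level for a gene, and folds against it are given as at least the ratio to that level. Between 62.2% and 87.6% of probe sets were above background on the efferent duct arrays and between 69.1% and 76.3% on the caput arrays.

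Differences were fitted with limma 3.58.1 in R 4.3.3, 1 model per tissue with 8 arrays and 4 groups, and p-values were adjusted by Benjamini and Hochberg with a threshold of 0.05. Tissue differences were contrasts of 1 model over 16 arrays. Means and SDs of 2 arrays are given in intensity, and fold changes come from the log2 model. In total 28 lists fixed before the data were seen, 17 of pathways or tissue functions and 11 of cell type markers, held 723 entries, of which 626 were measured. Each was tested with camera, which compares a list with all other genes, at its preset correlation of 0.01 and with an estimated correlation, adjusted over the lists and comparisons of a tissue. In the comparisons with sham or castrated vehicle, 84 tests per tissue, no camera call held with an estimated correlation (smallest adjusted p = 0.890 in the efferent duct and 0.310 in the caput). The members of each list were also adjusted over the list alone. Tables and figures used Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

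Genes were named by a rule set before the data were seen: per comparison with sham or castrated vehicle the 8 largest rises and falls among genes past the threshold whose groups did not overlap, up to 4 members per list, 5 each way in other comparisons, the smallest p values where few genes passed, and 10 fixed genes. After the values were seen, the largest changes among genes above background on all arrays were added, and list members were named only for lists past camera's test or with at least 0.5 of their genes called (in the efferent duct hormone comparisons 2 members of lists past camera's test). Etv5 and Dusp6 were also picked in the tissue comparison after their values were seen. Both array sets of the efferent duct were noticed in the data, not given by the labels.

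The fit was tested on simulated data with 100 changed genes at each of 2 sizes among 18193, and overlaps of comparisons with shared arrays were set beside 100 simulations of unchanged groups. The alternatives set beforehand were leaving out the 40% dimmest genes, quantile normalization, the mean of all probe sets of a gene, an intensity trend in the variance prior, 1 fit of all 16 arrays, the replicate number as a block, and each array left out in turn. For tissue differences the block joined arrays of the same treatment and number in both tissues. Setting values under 16 to 16 and fitting only the 4 arrays compared were added after the data were seen.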

Results

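RNA was measured on 16 one-colour Affymetrix arrays, 8 from the efferent ducts, the small tubules that carry sperm and fluid from the testis, and 8 from the caput, the first large region of the epididymis. Male mice of strain 129BL/6 had been sham operated or castrated. On day 14 after surgery they were injected with vehicle (100 µL of 10% ethanol in sesame oil), 0.015 mg testosterone propionate or 0.015 mg estradiol, and tissue was taken 12 hours later. Each tissue had 4 groups of 2 arrays: sham with vehicle, castrated with vehicle, castrated with testosterone propionate and castrated with estradiol. The number of arrays limits the precision: across all 18193 genes the median 95% interval of a group difference was the estimate ± 0.81 on the log2 scale in the efferent duct and ± 0.60 in the caput.

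In the efferent duct the 4 vehicle arrays and the 4 hormone arrays differed in signal quality, although the labels give one labelling kit for that tissue. The 3' over 5' ratio of actin, which rises when transcripts are shortened, was 3.11 to 3.87 (log2) on the vehicle arrays and 0.91 to 1.93 on the hormone arrays. The spiked Cre control, which is not mouse RNA, averaged 13.81 ± 0.27 (SD, n = 4) against 11.79 ± 0.24 in log2 intensity. The brightest probe set lay between 14456 and 19967 on the vehicle arrays and between 3218 and 4517 on the hormone arrays. In the caput the same 2 sets overlapped in Cre signal (12.60 ± 0.14 and 12.65 ± 0.28) and in their brightest probe set (9025 to 12021 and 8603 to 12111), while their 3' over 5' ratios of Gapdh did not (-0.509 to -0.387 on the vehicle arrays and -0.367 to -0.140 on the hormone arrays, log2). The comparisons of castrated with sham and of testosterone with estradiol each lie within one of these sets. The comparisons of either hormone with the castrated vehicle group cross them in the efferent duct. In the caput they cross the split in Gapdh ratio. Groups within a set could differ in quality too. In the caput the actin ratio was 1.08 and 1.20 on the testosterone arrays against 0.877 and 1.02 on the estradiol arrays, and the Gapdh ratio -0.207 and -0.140 against -0.367 and -0.329. On the castrated and sham caput arrays the actin ratio was 0.790 and 1.02 against 0.636 and 0.751, and the Gapdh ratio -0.387 and -0.454 against -0.509 and -0.481.

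**Figure D1:**
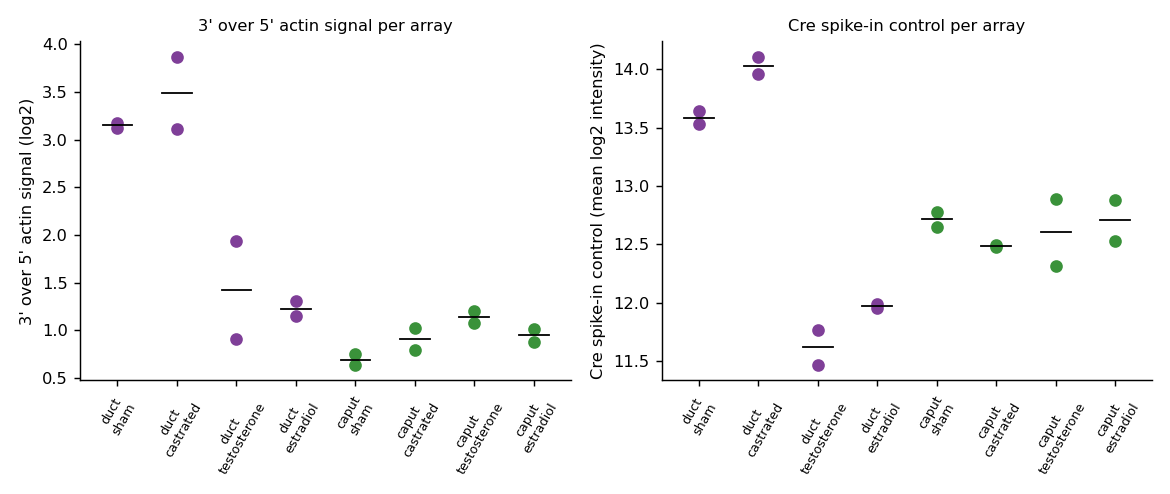
Each point is one array and each bar a group mean; the left panel gives the 3' over 5' actin signal (log2) and the right panel the mean log2 intensity of the Cre spike-in control, by tissue and treatment. The efferent duct vehicle arrays lie at 3.11 or above in the left panel and the efferent duct hormone arrays at 1.93 or below.

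Castration was compared with sham surgery in the caput to find the genes that depend on the testis there. Many secretory transcripts of the caput fell. Rnase10, a secreted ribonuclease-family protein of the proximal epididymis, fell from 10002 ± 438 to 27.0 ± 3.73 in intensity (mean ± SD, n = 2 arrays per group), 372-fold, with limma's adjusted p = 0.000469. The lipocalin genes Lcn8 and Lcn9, which encode carriers of small lipophilic molecules, fell 215-fold (adjusted p = 0.00608) and at least 974-fold (0.00484). Lypd8 fell 217-fold, Pate5 168-fold, Crisp4 91.3-fold, the protease gene Adam28 81.6-fold and the protease inhibitor gene Spink10 68.8-fold, with adjusted p values of 0.000469, 0.00132, 0.00289, 0.00200 and 0.000469. Lrcol1 fell at least 206-fold. Teddm2 went from 5725 ± 110.0 to 9.65 ± 8.19 and Rab26 from 528 ± 69.5 to 4.81 ± 4.31, each above background on 1 of the 2 castrated arrays.

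Of 32 measured caput and initial segment secretory genes, 17 fell, 1 rose and 14 did not pass (21 fell and 1 rose when adjusted over the list alone). Their median was -1.38 on the log2 scale (camera adjusted p = 6.69e-13, and adjusted p = 0.326 with an estimated correlation). Gpx5, an epididymal glutathione peroxidase, fell 2.62-fold from 8487 ± 140.1 (adjusted p = 0.0196), and Lcn5 stood at 2252 ± 52.8 against 11894 ± 179 (adjusted p = 0.0716). Of 15 beta-defensins, small antimicrobial peptides, 6 fell and 9 did not pass (8 fell and 1 rose over the list alone; camera adjusted p = 0.00203, and adjusted p = 0.584 with an estimated correlation). Defb21 fell 36.7-fold, Defb41 22.7-fold and Defb10 12.7-fold, and Defb4 at least 1.33-fold.

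Some genes of metabolism and protein folding fell too. Of 20 cholesterol synthesis genes 14 fell, 15 over the list alone, with a median of -1.34 (camera adjusted p = 8.13e-10, and adjusted p = 0.412 with an estimated correlation). The sterol reductase gene Tm7sf2 fell 7.15-fold, the dehydrogenase gene Nsdhl 4.46-fold and Cyp51 3.97-fold. Of 30 genes of endoplasmic reticulum folding and stress 15 fell and none of the others passed (20 fell and 1 rose over the list alone; camera adjusted p = 4.04e-07, and adjusted p = 0.326 with an estimated correlation). Sdf2l1 fell 3.46-fold, Manf 2.41-fold, Creld2 2.20-fold and Pdia6 2.12-fold. In oxidative phosphorylation 4 of 28 genes fell, Ndufa1 2.58-fold, Cycs 2.20-fold, Cox5a 1.76-fold and Ndufa4 1.58-fold, with a list median of -0.29 (4 fell over the list alone; camera adjusted p = 0.000858, and adjusted p = 0.427 with an estimated correlation).

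Some feedback genes of receptor tyrosine kinase and ERK signalling fell. Etv5, a transcription factor gene induced by ERK signalling, fell 17.7-fold from 1407 ± 31.2 to 80.2 ± 14.4, and the phosphatase genes Dusp6, Dusp4 and Dusp5 fell 5.38-, 4.57- and 3.35-fold. In that list 5 of 21 genes fell and 1 rose, 7 and 2 over the list alone (camera adjusted p = 0.0275, and adjusted p = 0.486 with an estimated correlation). Fkbp5, a widely used androgen-induced gene, fell 2.81-fold (adjusted p = 0.00539), while of the 43 measured genes of the androgen response list 8 fell and 4 rose (10 fell and 11 rose over the list alone), and the list did not pass (camera adjusted p = 0.727).

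Germ cell transcripts were lower as well. Of 23 sperm and germ cell markers 12 fell and 1 rose (18 and 1 over the list alone), with a median of -3.64 (camera adjusted p = 2.11e-08, and adjusted p = 0.412 with an estimated correlation). The protamine gene Prm2, which packs sperm DNA, went from 1743 ± 1692 to 20.6 ± 4.65, Prm1 fell 13.0-fold, and Gsg1, Tnp2 and Odf1 fell at least 27.1-, 26.7- and 16.4-fold.

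Other genes rose. Kif12 rose at least 16.3-fold, Sostdc1, a secreted antagonist of BMP and WNT signals, at least 10.9-fold, Wdr31 at least 5.10-fold, Caln1 at least 4.99-fold, Ces2a at least 4.31-fold, Rhov at least 4.18-fold and Myom3 at least 2.59-fold, and Nol4 was too dim for a fold. Among genes above background on all 4 arrays, Lrrtm1 rose 17.3-fold, the immunoglobulin alpha gene Igha from 33.2 ± 0.656 to 553 ± 222, Rasl11a 15.1-fold, Scg5 14.9-fold (adjusted p = 0.00105), Cltrn 13.8-fold, Socs3, a cytokine feedback gene, 13.4-fold, Cpn1 11.3-fold and Kcnh8 9.49-fold. The estrogen receptor gene Esr1 rose 1.82-fold to 984 ± 115 (adjusted p = 0.0423).

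Among groups, 4 of 25 interferon response genes rose and none fell, 10 over the list alone, among them Gbp2 (2.33-fold), Gbp3 (2.27-fold), Iigp1 (2.12-fold) and Irf1 (1.73-fold). The list's camera adjusted p was 0.00170, and its adjusted p = 0.412 with an estimated correlation. Of 22 macrophage and antigen presentation markers 3 rose, over the list alone too, Cd14 2.41-fold, Ptprc 1.99-fold and Tyrobp 1.58-fold (camera adjusted p = 0.0366, and adjusted p = 0.584 with an estimated correlation). Of 25 immediate early genes 5 rose and 1 fell, 7 and 1 over the list alone, with Fos up 6.70-fold, Gadd45b 3.08-fold, Maff 2.71-fold and Gadd45g 2.18-fold (camera adjusted p = 0.0176, and adjusted p = 0.412 with an estimated correlation). Of 27 apoptosis and regression genes 5 rose and 1 fell, 6 and 1 over the list alone; Bcl2, which protects from apoptosis, rose 4.58-fold, Bmf, which promotes it, 1.98-fold, Igfbp3 rose 2.46-fold, and the protease gene Mmp7 fell 9.88-fold (camera adjusted p = 0.0433, and adjusted p = 0.412 with an estimated correlation). Of 39 ciliated cell genes 9 rose and 2 fell, 18 and 4 over the list alone: the dynein genes Dynlrb2 and Dnah9 rose 3.38- and 2.93-fold, and Ccno and Cfap53 fell 7.29- and 2.85-fold (camera adjusted p = 0.00203, and adjusted p = 0.599 with an estimated correlation). Of 10 clear and narrow cell markers 6 rose and 2 fell, over the list alone too, without a list shift (camera adjusted p = 0.169): the proton pump genes Atp6v1b1 and Atp6v0a4 rose 3.58-fold and at least 2.72-fold, Kit rose 2.83-fold and the ammonium transporter gene Rhcg fell 35.6-fold.

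In all 6 comparisons with sham or castrated vehicle, 8 lists did not pass: androgen response, cell cycle, steroid receptors and metabolism, lymphocytes, smooth muscle, basal cells, clear and narrow cells, and Leydig and Sertoli cells. In total 2550 of 18193 genes passed limma's test (adjusted p under 0.05), 1437 higher and 1113 lower, and 1414 of them differed at least 2-fold. Without sham replicate 1 or 2, or castrated replicate 1 or 2, the count was 326, 523, 505 or 371, and it was 1503 with the mean of all probe sets, 1556 with the replicate number as a block, 4160 without dim probe sets, 4407 with an intensity trend and 0 with only the 4 arrays compared. In 1 simulated draw for this comparison the test recovered 66 of 100 genes changed 4-fold and 7 of 100 changed 2-fold, among 18193 genes. The draw changed far fewer genes than passed here, which makes the adjustment stricter. It does not give the power in these data.

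**Figure D2:**
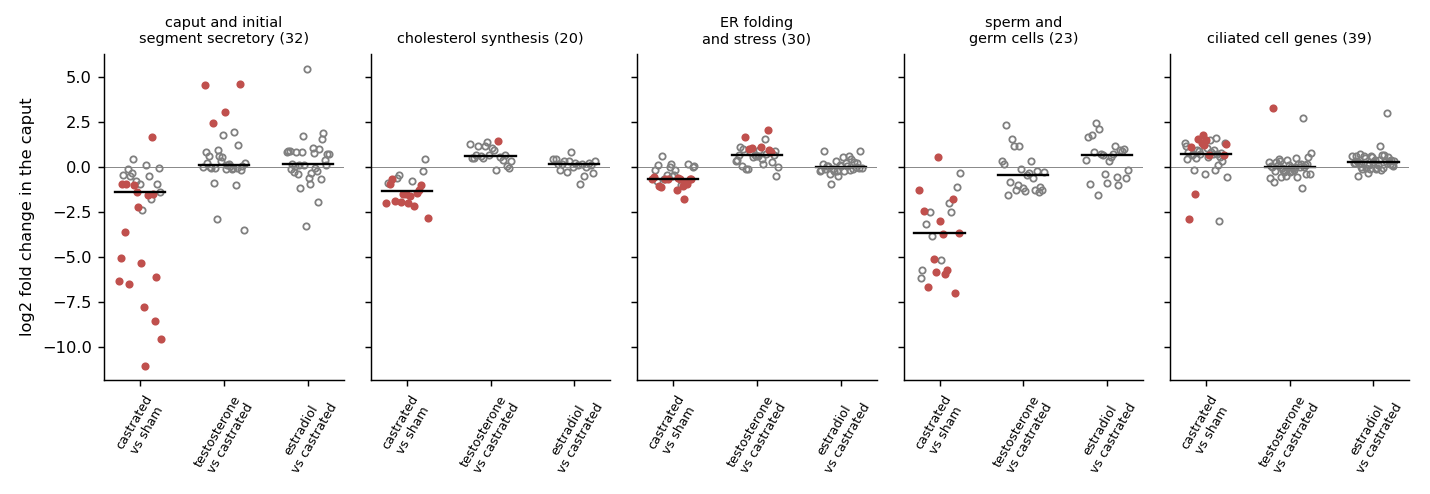
Log2 fold changes of the measured members of 5 gene lists in the caput (number of genes in brackets) for castrated against sham, testosterone against castrated and estradiol against castrated; filled points passed limma's test, open points did not, and bars are list medians. The castration medians are -1.38, -1.34, -0.66, -3.64 and 0.75 from left to right.

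Testosterone propionate was compared with vehicle in castrated animals to see which caput genes responded within 12 hours. Several secretory genes were higher again, while others that had fallen far after castration did not pass. Among the latter, Rnase10 had a log2 difference of 1.23, Lcn8 of 0.085 and Adam28 of -0.017, and Lcn9 and Teddm2 did not pass either. Adam7, a membrane protein of the caput epithelium, rose 23.6-fold from 255 ± 51.3 to 6002 ± 993 (mean ± SD, n = 2; limma adjusted p = 0.00496), against 8508 ± 192 in sham animals. Spink10 rose 24.0-fold (adjusted p = 0.00141), the protease inhibitor gene Spink5 12.8-fold, the lipocalin gene Lcn12 8.36-fold, the beta-defensin Defb41 10.8-fold and Crisp4 5.38-fold. Hpdl rose at least 45.1-fold to 427 ± 20.2 (adjusted p = 0.00141), and Cad, the first enzyme of pyrimidine synthesis, rose 14.7-fold.

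Asb11 rose 24.0-fold, Rhcg 11.2-fold, Ccno 9.66-fold and Kcnc4 at least 10.3-fold. Fkbp5 rose 3.05-fold to 1768 ± 72.1, beside 1628 ± 124 in sham animals. Mpp2 and Syt12, each above background on 1 castrated array, went from 11.3 ± 6.12 to 200.4 ± 17.3 and from 5.52 ± 4.16 to 85.8 ± 28.4, and Ccdc38 was at least 1.26-fold higher. Among falls above background on all arrays, Lrrtm1 fell 7.25-fold, the sodium-calcium exchanger gene Slc8a1 7.17-fold, Kif12 6.87-fold, Stc1 6.84-fold, the retinol transporter gene Stra6 5.89-fold, Defb35 5.68-fold, Rasl11a 4.95-fold and Crybb1 4.92-fold. Kntc1, Tead4, Atp12a and Speer4cos fell at least 1.85-, 1.31-, 1.25- and 1.16-fold, and Armh2, Speer5-ps1, Gm7444 and Tm6sf2 passed the test at levels too dim for a fold.

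Of 30 genes of endoplasmic reticulum folding and stress 7 rose and none fell, 22 over the list alone, with Sdf2l1 up 4.08-fold, Creld2 3.14-fold, Manf 2.16-fold and Dnajc3 2.11-fold (camera adjusted p = 6.54e-15, and adjusted p = 0.310 with an estimated correlation). Of 20 cholesterol synthesis genes only Nsdhl rose, 2.76-fold, while 11 rose over the list alone and the median was 0.62 (camera adjusted p = 2.11e-08, and adjusted p = 0.412 with an estimated correlation). Caput and initial segment secretory genes had 4 rises among 32 (8 rises and 2 falls over the list alone; camera adjusted p = 0.00912, and adjusted p = 0.596 with an estimated correlation), and beta-defensins 1 among 15 (3 rises and 1 fall over the list alone; camera adjusted p = 0.0118, and adjusted p = 0.600 with an estimated correlation). The collagen genes Col1a1 and Col1a2 rose, to 339 ± 2.13 from 84.8 ± 4.90 and 2.14-fold, 2 of 16 fibroblast and matrix markers (3 over the list alone; camera adjusted p = 0.0176, and adjusted p = 0.622 with an estimated correlation). Rasd1 rose 3.23-fold in the estrogen response list, where 1 of 37 rose (4 rose and 1 fell over the list alone; camera adjusted p = 0.0114, and adjusted p = 0.383 with an estimated correlation).

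Interferon response genes leaned down: none of 25 passed singly, 5 fell over the list alone, 24 of 25 were lower and the median was -0.45 (camera adjusted p = 5.50e-05, and adjusted p = 0.412 with an estimated correlation). Ribosome biogenesis genes passed as a list with no single call (median 0.18, camera adjusted p = 0.0275, and adjusted p = 0.622 with an estimated correlation). Gpx5 (4185 ± 759 against 3247 ± 246), Lcn5 (2222 ± 1160.0 against 2252 ± 52.8), Esr1 (959.9 ± 194 against 984 ± 115), Pgr, Slc9a3, Prm1 and Prm2 did not pass. The median of the 23 sperm markers was -0.42.

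The castrated and testosterone arrays of the caput overlapped in neither 3' over 5' ratio, as given above. In total 304 genes passed limma's test, 186 higher and 118 lower. Of these, 148 had fallen after castration and rose with testosterone, where independent lists would share 11.4, and 65 had risen and then fell, where independent lists would share 9.32, while 5 genes moved the same way in both. Both comparisons use the same castrated arrays. Simulated unchanged groups shared 0.02 opposite calls on average, but almost nothing is called in groups without change. That value is therefore no measure of the overlap that shared arrays give where many genes are called. The fold changes had a covariance across genes of -0.34 against a simulated -0.18 (correlation -0.41 against -0.50), a split would leave 1 castrated array on each side, and part of the excess may come from the shared controls. The 304 became 9, 12, 9 or 6 without castrated replicate 1 or 2 or testosterone replicate 1 or 2, 7 with the replicate number as a block, 118 with the mean of all probe sets, 1622 without dim probe sets, 1687 with an intensity trend, 926 with values under 16 set to 16 and 0 with only the 4 arrays compared, and the 213 opposite calls became 4 to 12 when any 1 array was left out and 7 with the replicate number as a block.

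Estradiol was compared with vehicle in castrated animals in the same way. No caput gene passed limma's test, with 2637 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.0501. The genes nearest to the threshold were Upk1a, a bladder-type membrane plaque gene, at 349.8 ± 11.2 against 50.5 ± 4.12 (log2 difference 2.79, 95% interval 2.42 to 3.17), the adrenergic receptor gene Adra2c (log2 difference 2.49, 95% interval 2.12 to 2.87), Odam at 15.5 ± 1.28 against 75.8 ± 6.47 and Rnf152 at 57.0 ± 3.42 against 194 ± 0.0594. Gng4 was at 313 ± 10.6 against 743 ± 7.02, and Fam131b was below background in both groups. Pgr, the progesterone receptor gene and a common estrogen target, was at 89.2 ± 22.9 against 43.6 ± 12.1 (adjusted p = 0.221). Fkbp5 (488 ± 20.9 against 579.6 ± 31.6), Gpx5, Lcn5, Esr1, Slc9a3, Prm1 and Prm2 did not pass.

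As lists, 16 fibroblast and matrix markers shifted up (14 higher; 9 rose and 1 fell over the list alone; median 0.69; camera adjusted p = 1.36e-05, and adjusted p = 0.427 with an estimated correlation). The 37 estrogen response genes shifted up too (25 higher; 6 rose and 1 fell over the list alone; median 0.40; camera adjusted p = 0.00198, and adjusted p = 0.326 with an estimated correlation). All 13 adipocyte markers were higher (median 0.84, camera adjusted p = 0.0176, and adjusted p = 0.640 with an estimated correlation), as were all 6 red blood cell markers (median 1.46, camera adjusted p = 0.0382, and adjusted p = 0.412 with an estimated correlation) and 29 of 39 ciliated cell genes (median 0.28, camera adjusted p = 0.0153, and adjusted p = 0.622 with an estimated correlation). None of these 3 lists held a call over the list alone. The count of 0 became 576 without dim probe sets, 724 with an intensity trend, 343 with values under 16 set to 16, 104 with all 16 arrays in 1 fit and 11 after quantile normalization.

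The 2 steroids were given at one dose and read at one time. Testosterone propionate is an ester of testosterone, whose A ring carries a ketone, and estradiol has an aromatic A ring. In the caput 386 genes differed between them by limma's test, 204 higher with testosterone and 182 higher with estradiol. Hpdl was 38.5-fold higher with testosterone (log2 difference 5.27, 95% interval 4.82 to 5.71; adjusted p = 0.00681), Spink5 13.8-fold, Lcn12 and Adam7 12.7-fold each, Lypd8 11.4-fold and Fkbp5 3.62-fold (1768 ± 72.1 against 488 ± 20.9). Kcnc4 and Zfp429 were at least 11.1- and 3.71-fold higher. With estradiol Sectm1b was higher, 459 ± 88.7 against 33.0 ± 13.7 (log2 difference -3.85, 95% interval -4.67 to -3.03), as were the serotonin receptor gene Htr5b (12.3-fold), the protease gene Adamts4 (10.6-fold), Tmem213 (9.59-fold), Bcat1 (9.55-fold), Pck1, a gluconeogenic enzyme gene that adipocytes also express (at least 3.36-fold), and Gm7444 (at least 1.86-fold). All 13 adipocyte markers were higher with estradiol as well, none past limma's test (median -1.67; camera adjusted p = 0.00135, and adjusted p = 0.545 with an estimated correlation, a list test chosen after the data were seen). The testosterone and estradiol arrays of the caput also had different 3' over 5' ratios, as given above.

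Cntn6, Sp8, Nlrp4e and Mptx1 passed with both groups below background. Pgr was 89.2 ± 22.9 with estradiol and 27.6 ± 3.54 with testosterone, a log2 difference of -1.67 with an interval of -2.37 to -0.98 that did not pass (adjusted p = 0.0555). Differences did not pass for Esr1 (-0.18, interval -0.66 to 0.30), Gpx5 (0.24, -0.31 to 0.78), Lcn5 (0.85, -0.82 to 2.51), Slc9a3 (1.52, -0.31 to 3.36), Prm1 (interval -3.11 to 1.11) or Prm2 (-1.06, -3.61 to 1.48). The 386 became 0, 13, 4 or 0 without testosterone replicate 1 or 2 or estradiol replicate 1 or 2, 153 with the mean of all probe sets, 9 with the replicate number as a block, 1270 without dim probe sets, 1396 with an intensity trend, 781 with values under 16 set to 16 and 0 with only the 4 arrays compared.

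**Figure D3:**
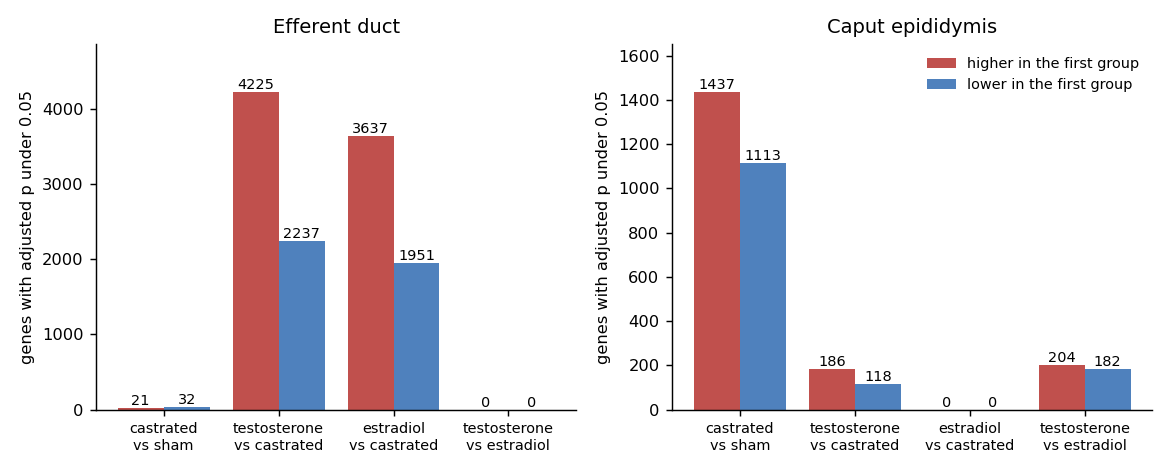
Number of genes with a limma adjusted p under 0.05 in each comparison, split into genes higher and lower in the group named first, for the efferent duct (left) and the caput epididymis (right); the y axes differ. The efferent duct bars for either hormone against castrated cross the 2 array sets and stand at 6462 and 5588 genes in total.

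In the efferent duct castration was compared with sham surgery in the same way. Cd52, a small surface glycoprotein that the epididymis adds to sperm, fell 44.3-fold from 4761 ± 320.1 to 107 ± 2.82 (mean ± SD, n = 2; limma adjusted p = 0.0128). Spink10 fell at least 198-fold and Serpina1f, a serpin gene, at least 49.1-fold. Neuropeptide Y (Npy) fell 37.3-fold, Odam 23.1-fold, Acbd7 14.3-fold, the prostaglandin synthase gene Ptgds 11.4-fold, Cuzd1 7.33-fold, and the pyrimidine pathway genes Cad and Cda 6.48- and 6.41-fold. The glutamate transporter gene Slc17a6 fell at least 9.67-fold, Cyp2d26 at least 1.70-fold, and Gm4988 went from 469 ± 169 to 12.1 ± 4.43.

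The calcium-binding protein gene S100g rose 4.47-fold to 139 ± 30.6, Serpinb1b 4.87-fold, the glycolytic gene Aldoc 4.40-fold and Srcap 3.19-fold. The ribonuclease gene Ang went from 8.14 ± 2.28 to 321 ± 146, above background on 1 of 2 sham arrays, and Gabra2, below background on both sham arrays, rose to 119 ± 21.9. Pcdh11x and A830018L16Rik rose at least 1.37- and 1.43-fold, Nmur2 at least 1.01-fold, and Glra3, Kcnh7, Cntn6 and 4930584F24Rik passed at levels too dim for a fold. Slc9a3, the sodium-hydrogen exchanger of fluid uptake, stood at 50.2 ± 43.9 against 509.6 ± 4.17 and did not pass (adjusted p = 0.117), nor did Lcn5 (22.2 ± 28.3 against 1965 ± 808), Gpx5, Fkbp5, Prm1, Prm2 or Pgr. Esr1 was 3623 ± 33.3 and 3801 ± 23.5, a log2 difference of -0.07 with a 95% interval of -0.63 to 0.49.

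Of 32 caput and initial segment secretory genes 4 fell in the efferent duct and 28 did not pass (11 fell and 1 rose over the list alone; median -2.83; camera adjusted p = 4.25e-08, and adjusted p = 0.890 with an estimated correlation). No single member passed in the other lists that shifted, each with an adjusted p of 0.890 with an estimated correlation. All 20 cholesterol synthesis genes were lower (7 over the list alone; camera adjusted p = 3.66e-07), 14 of 15 beta-defensins (5 over the list alone; 5.52e-05), all 28 oxidative phosphorylation genes (0; 0.000127), 20 of 23 sperm markers (0; 0.00269) and 19 of 26 fluid transport and endocytosis genes (5; 0.00610). Lower lists also included macrophage markers (18 of 22; 4 over the list alone; 0.0123) and fibroblast markers (12 of 16; 4 fell and 1 rose over the list alone; 0.0201), and 34 of 39 ciliated cell genes were higher (0; 0.000170). In total 53 genes passed, 21 higher and 32 lower, and only 19 of them were above background in both groups. The count was 18 (16 higher and 2 lower), 0, 23 or 91 without sham replicate 1 or 2 or castrated replicate 1 or 2, 34 with the mean of all probe sets, 8 with the replicate number as a block, 0 with only the 4 arrays compared, 85 after quantile normalization, 490 without dim probe sets, 698 with an intensity trend, 241 with values under 16 set to 16 and 991 with all 16 arrays in 1 fit. In 1 simulated draw for this comparison the test recovered 0 of 100 genes changed 4-fold. A draw with the same means, spreads and group size for testosterone against estradiol in this tissue recovered 33 of 100. The draws therefore do not measure the power of this comparison. Smaller changes than those called stay open.

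Either hormone differed from castrated vehicle in many efferent duct genes, in comparisons that cross the 2 array sets described above. With testosterone 4225 genes were higher and 2237 lower, and with estradiol 3637 and 1951, by limma's test. The median of all genes stood at 0.23 and 0.25 (log2), and at 0.17 and 0.09 after quantile normalization. With testosterone, Serpina1f was at least 10.4-fold higher, Wfdc6a, a protease inhibitor family gene, at least 17.8-fold, and Fkbp5 8.36-fold, at 765 ± 35.3. The beta-defensin Defb2 went from 19.8 ± 25.9, above background on 1 castrated array, to 534 ± 111. Of 32 caput and initial segment secretory genes 7 rose and 1 fell (3 rose over the list alone), and the list did not pass (camera adjusted p = 0.485). Pdia4, a protein disulfide isomerase gene, rose 22.7-fold, the heme oxygenase gene Hmox1 18.1-fold, Susd3 17.1-fold, Hddc3 16.5-fold, Acp5 16.4-fold, Sncg from 56.8 ± 13.1 to 898 ± 2.19, Cygb 15.6-fold and the adipocyte hormone gene Lep 14.8-fold. Slc9a3 was 319 ± 176 against 50.2 ± 43.9 and rose 7.45-fold (adjusted p = 0.0319). Gabra2 fell 27.0-fold, Adamts4 14.4-fold, Bnip5 13.3-fold, Prkg2 8.23-fold, Cntn3 7.63-fold, Gm34006 7.63-fold, Gm4432 7.41-fold and Slc22a29 7.17-fold. The background was 2.33 to 3.97 on the hormone arrays and 8.09 to 14.3 on the vehicle arrays. A fall can therefore end at a level that would count as background on the vehicle arrays, and its fold is then uncertain. Near background, also higher with testosterone were Tpsab1 at least 1.73-fold, Cwh43 (below background before, 83.9 ± 101 after), Acta1 at least 2.64-fold, Fam171a1 at least 5.64-fold and Chst4 at least 2.77-fold. Lower with testosterone were Gm4788 at least 3.01-fold, Taar1 at least 2.97-fold, Elobl (2.22 ± 1.94 against 164 ± 55.0, the dimmer group above background on 1 of 2 arrays), Tmprss11f at least 3.47-fold, E330017L17Rik at least 6.78-fold and Vmn1r43 at least 2.65-fold. Rps16, Syt16 and Gzmd passed at levels too dim for a fold.

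With estradiol the kallikrein genes Klk1b21 and Klk1b27 were at least 58.7- and 48.7-fold higher and the acute phase gene Saa2 at least 14.2-fold. The neutrophil genes S100a9 and S100a8 rose 21.8- and 13.3-fold, Acp5 19.3-fold, Pdia4 18.4-fold, Plin4 16.6-fold, Cygb 16.5-fold, Mydgf 13.9-fold and Sox18 13.2-fold. Tmem18 fell 16.6-fold, Bnip5 13.3-fold, Ascl2 10.5-fold, Phkg1 9.01-fold, Cldn9 8.23-fold, Grik3 7.88-fold, 1700110K17Rik 7.77-fold and Prkg2 7.74-fold. Ascl2 with estradiol lay under the background of the vehicle arrays, so the size of its fall is uncertain. Esr1 fell 2.05-fold with testosterone and 2.27-fold with estradiol, and the testosterone difference stood at 0.10 (log2) after quantile normalization. Pgr was 67.7 ± 14.1 with testosterone, lower than in castrated animals (adjusted p = 0.0238), and 232 ± 44.5 with estradiol (adjusted p = 0.0746). Fkbp5 rose with estradiol too, 2.58-fold (adjusted p = 0.0218). Slc9a3 did not pass with estradiol, nor did Gpx5, Lcn5, Prm1 or Prm2 with either steroid. Also higher with estradiol were Arhgap10 at least 4.06-fold, Snai1 at least 2.58-fold, Dbh at least 7.84-fold, Unc93b1 at least 4.78-fold, Smco2 at least 2.53-fold and Mrpl23 2.92-fold. Lower with estradiol were Gm4788 at least 2.17-fold, Gm19835 at least 3.34-fold and Olfr66 at least 2.35-fold. Hs3st2, Sox30, Gm4871, Cyp3a25 and Gzmd passed at levels too dim for a fold.

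As lists, endothelial markers shifted up with both steroids (8 of 12 rose with each; 9 with testosterone and 10 with estradiol over the list alone), with Cdh5 up 6.44-fold and Eng 5.54-fold with testosterone and Eng 7.82-fold and Tie1 6.07-fold with estradiol. The camera adjusted p values were 0.0147 and 0.00317, and the adjusted p = 0.890 with an estimated correlation for both. Macrophage markers shifted up (11 of 22 rose with testosterone and 9 rose and 1 fell with estradiol; 11 alone, and 10 and 1, over the list alone), Adgre1 7.95-fold and Cd68 7.95-fold with testosterone and C1qa 7.13-fold and C1qc 7.25-fold with estradiol (camera adjusted p = 0.0244 and 0.0497, and adjusted p = 0.890 with an estimated correlation). Cytosolic ribosomal protein genes shifted down (11 fell and 1 rose of 22 with testosterone, 12 and 1 over the list alone; 8 fell and 2 rose with estradiol, over the list alone too), Rps24 3.17- and 2.61-fold, with camera adjusted p = 0.000329 and 0.0148, and adjusted p = 0.890 with an estimated correlation. Their medians of -0.64 and -0.29 turned to 0.41 and 0.45 after quantile normalization, with camera adjusted p = 0.0391 and 0.00412. The direction of this list therefore depends on the normalization.

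Both steroid comparisons share the castrated arrays as well as the array sets. They called 4841 genes with the same sign, where independent lists would share 845 rises and 239.9 falls, and 8 with opposite signs. Simulated unchanged groups shared 0, which follows from their having almost no calls. The covariance across genes was 1.58 against a simulated 0.22. Without estradiol replicate 1 the estradiol count was 0 and the overlap 0; without estradiol replicate 2 they were 2059 and 1904, without castrated replicate 1 3508 and 3055, and without testosterone replicate 1 the testosterone count was 2442 and the overlap 2142, and 4201 without testosterone replicate 2. With only the 4 arrays compared the counts were 2339 and 2549, and 4015 and 3206 with the mean of all probe sets. Of the 53 castration calls 37 moved the other way with testosterone, 24 up and 13 down, where independent lists would share 7.43 and 2.58. Simulated unchanged groups shared 0, again because almost nothing is called in them. The castration and testosterone comparisons share the castrated arrays too. The fold changes had a covariance across genes of -0.72 against a simulated -0.22 (correlation -0.47 against -0.50), so part of the opposite movement may come from the shared arrays, and the testosterone comparison crosses the array sets. This count of 37 was 0 without sham replicate 2, 9 without sham replicate 1, 16 and 18 without testosterone replicate 1 or 2, 20 and 75 without castrated replicate 1 or 2, and 6 with the replicate number as a block.

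Testosterone and estradiol could be compared within one set of efferent duct arrays. No gene passed limma's test, with 1467 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.0745, and counts of 69 without dim probe sets, 118 with an intensity trend, 65 with values under 16 set to 16 and 132 with all 16 arrays in 1 fit. Nearest to the threshold were the zinc transporter gene Slc30a3, 222 ± 61.1 with testosterone against 16.2 ± 3.77 with estradiol (log2 difference 3.77, 95% interval 3.07 to 4.47), Ascl2 (53.3 ± 4.24 against 5.65 ± 0.790), Sectm1b (63.8 ± 9.24 against 557 ± 72.9; -3.13, interval -3.70 to -2.55) and the troponin gene Tnnc1 (17.6 ± 2.97 against 107 ± 3.35). 9130001E16Rik was below background with estradiol and Nmur2 with both steroids. Slc9a3 was 319 ± 176 with testosterone and 26.0 ± 1.25 with estradiol (log2 interval 1.65 to 5.35), Fkbp5 765 ± 35.3 and 237 ± 28.1 (1.70, 0.97 to 2.42), Pgr 67.7 ± 14.1 and 232 ± 44.5 (-1.78, -2.39 to -1.17) and Esr1 1791 ± 436 and 1602 ± 167 (0.14, -0.42 to 0.70). Lcn5, Gpx5, Prm1 and Prm2 had wide intervals, -2.00 to 5.98 for Lcn5 and -7.01 to 5.86 for Gpx5. In 1 simulated draw for this comparison the test recovered 33 of 100 genes changed 4-fold and 0 of 100 changed 2-fold, among 18193 genes. A draw with the same means, spreads and group size for castrated against sham recovered 0 of 100 changed 4-fold. The draws therefore do not measure the power of this comparison.

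**Figure D4:**
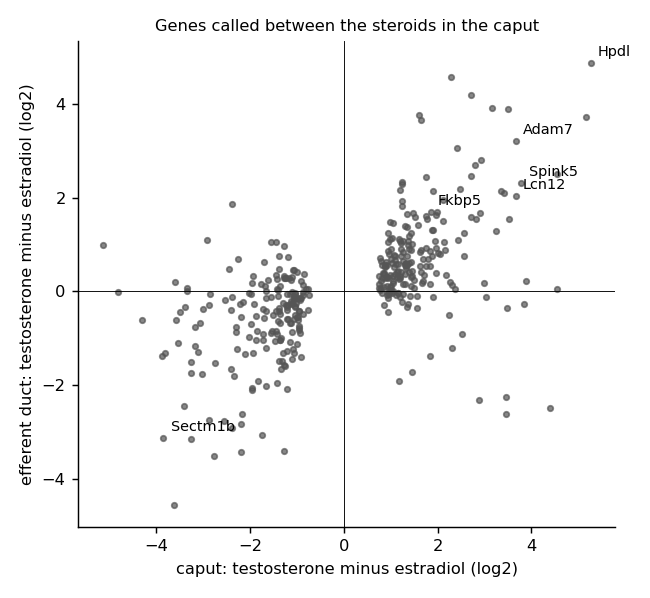
Log2 difference between testosterone and estradiol in the caput (x axis) and in the efferent duct (y axis) for the 386 genes that passed limma's test in the caput, 1 point per gene. Of these, 313 had the same sign in both tissues.

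The effects of each treatment were also compared between tissues, by the difference of the efferent duct and caput effects in 1 limma fit over all 16 arrays. Tissue and labelling kit cannot be told apart in this design. By the labels each treatment effect lies within 1 kit, although the efferent duct vehicle and hormone arrays differed in signal quality. The scale of an effect may differ between kits, so the limit holds for all tissue differences below. The 3' over 5' actin ratio was 3.11 to 3.87 (log2) on the efferent duct vehicle arrays and 0.64 to 1.02 on those of the caput. Between sham tissues 9903 genes differed (4263 higher in the efferent duct, 5640 higher in the caput). Higher in the sham efferent duct were Fndc7 (142-fold), the metabolic kinase gene Pdk4 (88.6-fold), Mmd2 (76.8-fold), the transcription factor gene Hnf4a (70.8-fold), Ccdc30 (61.5-fold), Slc9a3 (17.5-fold), Esr1 (7.06-fold, 3801 ± 23.5 against 539 ± 39.9) and Pgr (3.84-fold). Higher in the caput were Lap3 (193-fold), Teddm2 (116-fold), the cystatin gene Cst12 (103-fold), Cryba4 (103-fold), St8sia6 (77.2-fold), Gpx5 (67.7-fold), Fkbp5 (4.66-fold) and Prm1 (6.22-fold), while Lcn5 and Prm2 did not pass. Near background on one side, the efferent duct was higher for Kcnj16 (1398 ± 60.6 against 11.7 ± 13.1, the dimmer group above background on 1 of 2 arrays), Ackr4 at least 127-fold, Cyp4a12a at least 12.2-fold and Sult1d1 at least 65.8-fold. The caput was higher in this way for Unc93b1 at least 8.15-fold, Enpp5 (3677 ± 875 against 13.9 ± 7.47, the dimmer group above background on 1 of 2 arrays) and Tcl1b3 at least 55.5-fold.

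The castration effect differed between tissues for 587 genes, 231 with a higher and 356 with a lower value in the efferent duct. For 443 of them the 2 estimates had opposite signs, without a test of either alone. Some of these had a small effect on one side, as Odam with -4.53 in the efferent duct and 0.35 in the caput. Only 53 genes passed for castration in the efferent duct. Etv5 was 92.6 ± 24.5 in sham and 89.7 ± 20.2 in castrated efferent duct, beside its fall in the caput, a difference of 4.11 on the log2 scale (adjusted p = 0.00319), and Dusp6 differed by 2.65. C1qtnf9, P4ha2, Cttnbp2, Pla2g5 and St3gal2 had lower castration effects in the caput than in the efferent duct, with differences of 5.74, 5.07, 5.01, 4.86 and 4.12. Odam, Ces5a, the chloride exchanger gene Slc26a3, Syn2 and Pdzk1ip1 had lower castration effects in the efferent duct than in the caput, with differences of -4.88, -4.27, -3.91, -3.66 and -3.61. Esr1, Pgr, Gpx5, Lcn5, Slc9a3, Fkbp5, Prm1 and Prm2 did not pass here. The count was 343 without efferent duct sham replicate 1, and 154, 218, 184 or 145 without caput sham replicate 1 or 2 or caput castrated replicate 1 or 2, and 300 with the mean of all probe sets, 1038 without dim probe sets, 1104 with an intensity trend and 1469 with values under 16 set to 16. The series description says that both tissues were collected from each sample but not which arrays share an animal. With arrays of the same treatment and number in both tissues as a replicate block, no gene passed for castration. That fit has fewer residual degrees of freedom by construction, so the lost calls do not show that pairing removes the difference. Differences also passed for genes with a group above background on at most 1 of its arrays, which have no order: Fgg, Ntsr1, Tbc1d21, Nell1 and Fbxw14 on the higher side and Defb11, Cyp4a12a, Cwh43 and Ltf on the lower side.

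The testosterone effect differed between tissues for 5823 genes and the estradiol effect for 4706, counts that include the difference between the efferent duct array sets. Larger with testosterone in the efferent duct were Acp5 (4.79 on the log2 scale), Cygb (4.33), Slpi (4.23), Lgmn (4.11), Tmem45b (4.05) and Fkbp5 (1.45), and lower were Eppk1 (-3.96), Bnip5 (-3.91), Prkg2 (-3.88), Bcl11b (-3.62), Atp2b4 (-3.34) and Esr1 (-0.99, which was 0.22 after quantile normalization). Larger with estradiol were Gsta3 (4.25), Cygb (4.05), Acp5 (4.004), Hddc3 (3.89), Lap3 (3.76) and Fkbp5 (1.61), and lower were Bnip5 (-3.69), Fam161a (-3.52), Prkg2 (-3.26), Abhd2 (-3.23), Ttc9 (-3.21) and Esr1 (-1.32, which was -0.45 after quantile normalization and did not pass). With the mean of all probe sets the counts were 3702 and 2852. Differences also passed for genes with at most 1 array above background in at least 1 of their groups, which have no order: for testosterone Cd209g, Smco2 and Fam171a1 on the higher side and Neurod6, Vmn1r43, Syt16, Defb7 and Gzmd on the lower side, and for estradiol Cd209g, Gjb5, 4930568G15Rik, Ccl2 and Pgam2 on the higher side and Cyp3a25, Krt6b, Gm10228, Glp1r and Gzmd on the lower side.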

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

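All tests weighed in this part were chosen after related values had been seen, while the tissue contrasts themselves were planned. What marked the results below was a difference between tissues in the effect of one treatment, tested as a contrast in 1 limma fit over 16 arrays. Tissue and labelling kit changed together, so the scale of an effect may differ between kits. Only named genes with every one of the 4 groups above background on at least 1 array are listed, a limit set after the values were seen: it kept 31 of 49 genes for castration, 32 of 59 for testosterone and 29 of 52 for estradiol, and left out 18, 27 and 23.

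The castration effect differed between tissues for 587 genes in the main fit, and for none with arrays of the same treatment and number as a replicate block. The blocked fit has fewer residual degrees of freedom. For 443 of the 587 the estimates in the tissues had opposite signs, without a test of either alone. Higher in the efferent duct by log2 difference were C1qtnf9 5.74, P4ha2 5.07, Cttnbp2 5.01, Pla2g5 4.86, St3gal2 4.12, Etv5 4.11. Next came Dusp6 2.65, Tm7sf2 2.30, Cfap53 1.81, Cad 1.62, Aldoc 1.303, Srcap 1.21. Then followed Creld2 1.06. Lower in the efferent duct were Odam -4.88, Ces5a -4.27, Slc26a3 -3.91, Syn2 -3.66, Pdzk1ip1 -3.61, Cltrn -3.44. After these came Cpn1 -3.20, Kit -2.12, Scg5 -2.09, Ptgds -2.03, Cd52 -1.85, Cuzd1 -1.85. These were followed by Gadd45g -1.53. With a group above background on 1 of its 2 arrays, so that the fitted log2 difference depends on values under background and gives no order, Adam28 (5.83), Ang (4.25) and Teddm2 (6.74) were higher and Defb11 (-9.26) and Defb2 (-8.46) lower in the efferent duct.

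The testosterone effect differed for 5823 genes, a count that crosses the efferent duct array sets. Higher in the efferent duct by log2 difference were Acp5 4.79, Cygb 4.33, Slpi 4.23, Lgmn 4.11, Tmem45b 4.05, Hddc3 3.92. Next came Crybb1 3.51, Cd68 3.003, Pdia4 2.94, Cdh5 2.76, Adgre1 2.75, Lrrtm1 2.46. Then followed Kif12 2.27, Eng 2.24, Slc8a1 2.18, Fkbp5 1.45. Lower in the efferent duct were Eppk1 -3.96, Bnip5 -3.91, Prkg2 -3.88, Bcl11b -3.62, Atp2b4 -3.34, Gm4432 -3.06. After these came Adamts4 -2.06, Ccno -1.86, Rps24 -1.72, Dnajc3 -1.67, Cad -1.31, Esr1 -0.99. With a group above background on 1 of its 2 arrays, so that the fitted log2 difference depends on values under background and gives no order, Defb2 (5.96), Rasl11a (3.98), Sncg (4.27) and Susd3 (2.12) were higher in the efferent duct.

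The estradiol effect differed for 4706 genes, with the same limit. Higher in the efferent duct by log2 difference were Gsta3 4.25, Cygb 4.05, Acp5 4.004, Hddc3 3.89, Lap3 3.76, Pdia4 3.59. Next came Plin4 3.57, Mydgf 3.31, Sox18 3.02, Odam 2.78, C1qc 2.58, C1qa 2.45. Then followed Eng 2.30, Tie1 2.25, Rnf152 2.12, Fkbp5 1.61, Mrpl23 1.49, Gng4 1.02. Lower in the efferent duct were Bnip5 -3.69, Fam161a -3.52, Prkg2 -3.26, Abhd2 -3.23, Ttc9 -3.21, 1700110K17Rik -2.94. After these came Ascl2 -2.78, Cldn9 -2.47, Tmem18 -2.11, Rps24 -1.56, Esr1 -1.32. The value for Ascl2 rests on an efferent duct estradiol level under the background of the vehicle arrays.

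The first pattern was the large number of efferent duct genes that differed between either hormone and castrated vehicle, 6462 and 5588. The tables argue against the hormones as the only difference between the sets, since the 3' over 5' actin ratios were parted by 1.18 on the log2 scale, more than the range of 1.02 inside a set. The Cre control, which is not mouse RNA, was parted by 1.55 with a range of 0.575, as a technical difference between the vehicle and hormone arrays can give. Gaps for Gapdh (0.733) and bioB (0.124) were smaller than their ranges of 1.02 and 1.35. The sets were noticed in these same data, so the gaps describe them and are no independent test. Part of these genes may still respond to the hormones, and for single genes hormone and array set cannot be told apart in this tissue, because each set holds only one kind of treatment.

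The second pattern was that 213 of the 304 caput genes called with testosterone had moved the other way after castration. Most of the 2550 genes called for castration in the caput did not pass with testosterone. Both comparisons share the castrated arrays. Chance values of those arrays as the only cause are argued against by the comparison of testosterone with estradiol, which uses none of them: 64.9% of the 1113 genes that had fallen were higher with testosterone, against 44.7% of 10494 other genes, and 63.5% to 66.2% without any 1 hormone array. Of the 1437 that had risen, 72.8% were lower with testosterone against 55.3%, and in the efferent duct 71.9% of 32 were higher (58.2% of others) and 66.7% of 21 lower (41.8%). The other genes were limited to those above background and the castration genes were not. The testosterone and estradiol arrays of the caput also had different 3' over 5' ratios. A response to testosterone that estradiol does not share is a hypothesis these values leave open, and it may apply to part of the genes only.

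The third pattern was that genes called between the steroids in the caput mostly differed in the same direction in the efferent duct. Lists did not all do so. In the caput 31 of 39 ciliated cell genes and 19 of 23 sperm markers were higher with estradiol (camera adjusted p = 0.116 and 0.200). In the efferent duct 36 of 39 and 21 of 23 were higher with testosterone. Genes of endoplasmic reticulum folding and stress were higher with testosterone in 29 of 30 cases in the caput but 17 of 30 in the efferent duct. For cholesterol synthesis it was 19 of 20 and 9 of 20, and for interferon response 4 of 25 and 15 of 25. Beta-defensins and adipocyte markers kept their direction. Immediate early and ERK feedback genes did too, without passing camera's test in the efferent duct. Among the 386 genes that passed in the caput, 81.1% had the same sign in the efferent duct, against 55.2% of other genes, and 75.4% to 81.6% without any 1 efferent duct array, which argues against unrelated differences. Among the 309 above background in both tissues it was 85.4%, and the steroid differences correlated across genes at 0.151 for all genes and 0.405 for those above background. A difference between the steroids common to both tissues is a hypothesis. If the duplicates are separate animals, differences between single animals carried to both tissues are argued against: the difference between the duplicates of a treatment correlated between tissues at -0.0019 to 0.0907 among genes above background, beside the 0.405. The labels do not say that they are separate animals, so a difference between pools or in the handling of the groups stays open.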

How the results depend on the processing

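Fitting only the 4 arrays compared and setting values under 16 to 16 were chosen after seeing the data, and all other alternatives before. Counts that moved by more than 1.5 times follow by setting, in the order castration, testosterone, estradiol and steroid difference, and the cause was not tested unless stated. Without dim probe sets the caput counts were 4160, 1622, 576 and 1270, the efferent duct gave 490 for castration and 69 between steroids, the castration tissue difference 1038, and the overlaps of castration with testosterone 322 and 966 (efferent duct, caput) and of the steroids in the caput 213. With an intensity trend the caput gave 4407, 1687, 724 and 1396, the efferent duct 698 and 118, the tissue difference 1104 and the overlaps 432, 985 and 271. With values under 16 set to 16 the caput gave 926, 343 and 781 for all but castration, the efferent duct 241 and 65, the tissue difference 1469 and the overlaps 154, 614 and 150. With all 16 arrays in 1 fit, castration in the efferent duct gave 991, the steroids there 132, estradiol in the caput 104, and overlaps of 622 (castration with testosterone, efferent duct) and 18 (steroids, caput).

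With the mean of all probe sets the efferent duct counts were 34, 4015 and 3206, the caput counts 1503 and 118 with 153 between steroids, the tissue differences 300, 3702 and 2852, and the overlaps 21 and 89 for castration with testosterone and 2628 for the steroids in the efferent duct. Quantile normalization gave 85 for castration in the efferent duct, 11 for estradiol in the caput, overlaps of the steroids of 3183 (efferent duct) and 5 (caput), and 25 list calls in the efferent duct. It turned the sign of Esr1 (0.10) and Rps16 (0.024) under testosterone in the efferent duct, of the Esr1 tissue difference under testosterone (0.22), and of the cytosolic ribosomal protein list under testosterone (0.41) and estradiol (0.45). With only the 4 arrays compared, whose residual degrees of freedom are fewer by construction, castration gave 0 in both tissues, the caput hormone and steroid comparisons 0, and the efferent duct hormones 2339 and 2549.

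Leaving out 1 array, where the lone array is assumed to vary like the other groups, gave these lowest and highest counts. Efferent duct: castration 0 to 91, testosterone 2442 to 4738, estradiol 0 to 3912, steroids 0 to 0, list calls 8 to 18. Caput: castration 326 to 523, testosterone 6 to 12, estradiol 0 to 0, steroids 0 to 13, list calls 21 to 26. Tissue differences: castration 145 to 662, testosterone 4447 to 5615, estradiol 3426 to 4673, sham 8356 to 8780. Overlaps of castration with testosterone: 0 to 75 (efferent duct) and 4 to 12 (caput), and of the steroids 0 to 3446 and 0 to 0. Fewer arrays are part of the construction of these fits.

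With the replicate number as a block, castration gave 8 genes in the efferent duct and 1556 in the caput, testosterone in the caput 7, the steroids in the caput 9, the castration tissue difference 0, and the overlaps of castration with testosterone 6 and 7. A block leaves fewer residual degrees of freedom by construction. Same-numbered arrays deviated together little or not at all. Over all genes the correlations were -0.05 to 0.07 within the efferent duct, -0.03 to 0.02 within the caput and -0.02 to 0.03 between tissues. Among genes above background in both tissues they were -0.0019 to 0.0907 between tissues. The numbers therefore gave little sign of pairing.

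Single genes and lists were followed through the settings, except that lists, overlaps and tissue differences were not run with only the 4 arrays compared, tissue differences are already fits of all 16 arrays, and genes removed as dim have no value without dim probe sets. In leave-one-out fits 1307 gene results kept their side of the threshold, 701 fell short of it and 8 newly passed, and 616, 33 and 23 list results did so. The gene results that stayed and that fell short numbered 129 and 179 with only the 4 arrays compared, 298 and 121 with the replicate block, 336 and 84 with the mean of all probe sets, 377 and 35 with quantile normalization, 258 and 34 with all 16 arrays in 1 fit, 333 and 29 with values under 16 set to 16, 394 and 3 with an intensity trend, and 278 and 0 without dim probe sets. In the efferent duct 19 of 53 castration calls were measured in both groups.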

Other observations

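The list tests between the steroids in this part were chosen after the data were seen. In the caput, 29 of 30 genes of endoplasmic reticulum folding and stress were higher with testosterone than with estradiol, 7 of them past limma's test (median 0.59 on the log2 scale; camera adjusted p = 5.48e-17, and adjusted p = 0.0860 with an estimated correlation). Cholesterol synthesis genes were higher in 19 of 20 cases (1 passed; adjusted p = 3.34e-08, and adjusted p = 0.437 with an estimated correlation) and beta-defensins in 13 of 15 (3 passed; adjusted p = 0.000113, and adjusted p = 0.437 with an estimated correlation). All 13 adipocyte markers were higher with estradiol, with a median of -1.67 and no single call (adjusted p = 0.00135, and adjusted p = 0.545 with an estimated correlation). Interferon response genes were higher with estradiol in 21 of 25 cases (adjusted p = 0.00390, and adjusted p = 0.437 with an estimated correlation). So were immediate early genes in 20 of 25 (1 passed; adjusted p = 0.0142, and adjusted p = 0.419 with an estimated correlation) and ERK feedback genes in 16 of 21 (2 passed; adjusted p = 0.0406, and adjusted p = 0.437 with an estimated correlation).

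In the efferent duct, where no single gene passed between the steroids, 36 of 39 ciliated cell genes were higher with testosterone (median 0.35; camera adjusted p = 1.52e-05, and adjusted p = 0.727 with an estimated correlation). All 22 cytosolic ribosomal protein genes were higher with estradiol (median -0.26; adjusted p = 3.29e-05, and adjusted p = 0.727 with an estimated correlation), as were 26 of 28 oxidative phosphorylation genes (adjusted p = 0.00702) and 26 of 30 ribosome biogenesis genes (0.0308). Fluid transport and endocytosis genes were higher with testosterone in 20 of 26 cases (0.0308), sperm markers in 21 of 23 (0.0312) and beta-defensins in 11 of 15 (0.0342), and smooth muscle markers were higher with estradiol in 12 of 14 (0.0312), red blood cell markers in 5 of 6 (0.0342) and adipocyte markers in 10 of 13 (0.0410). None of the 10 passed with an estimated correlation. Of the caput castration genes, 140 fell after castration and were called higher with testosterone than with estradiol, where independent lists would share 12.5. Another 78 rose and were called lower, where they would share 14.4, and the other sign pairs had 18 (11.1) and 9 (16.1). Both sets of calls use 1 estimate of the spread per gene from the same fit. The lists are therefore not independent, and overlaps of either sign can exceed these expectations.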
